A study of Saccharomyces cerevisiae and Schizosaccharomyces pombe with 10 samples.

How the data were processed

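Nascent RNA, the RNA that is still held by transcribing polymerases on chromatin, was profiled by long-read sequencing in budding yeast (Saccharomyces cerevisiae, strain BY4741) and fission yeast (Schizosaccharomyces pombe, strain L972, wild type). Per the labels' protocols, cells were grown in rich glucose medium at 30 °C and harvested in exponential growth. Nascent RNA was isolated, its 3' ends were ligated to a DNA adaptor that carries random bases, and cDNA was made with a SMARTer kit, amplified over a few PCR cycles and sequenced on a Pacific Biosciences instrument. The series lists 10 samples. Of these, 2 are S. cerevisiae nascent RNA replicates and 1 is S. pombe nascent RNA. The other samples, 3 of a galactose-driven splicing reporter, 3 of the same reporter with a changed 5' splice site and 1 of the gene YDR381W in the reporter strain, were not analysed here.

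The deposited files hold genome alignments, 1 line per alignment of a consensus read, with its start, end, strand and aligned blocks. The fifth field of the deposited files is a score, which was 40 in every line and was not used. The submitters' processing notes name the build sacCer3 and cutadapt version 1.8. They name sacCer3 for the S. pombe sample too. That cannot be the build of its alignments, since all but 454 lie on chromosomes I to III of fission yeast, and 451 of these 454 on its mitochondrial genome. The aligner and its settings were not given in the sources used here. The S. cerevisiae alignments of both replicates stand together and the read names do not tell the replicates apart, so each species was treated as 1 pool of reads and no spread between replicates could be given. The read names show 5 sequencing movies for S. cerevisiae, 4 earlier and 1 later, and 4 for S. pombe, 2 earlier and 2 later. Values were computed again within the earlier and the later movies. Reads of the later S. cerevisiae movie were longer (median 185 nt against 101 nt in the earlier ones), so S. cerevisiae values by movie also differ in read length. The S. pombe movies come from the same sample and are not replicates.

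Depth was 101128 alignments of 100834 reads for S. cerevisiae and 16126 alignments of 16122 reads for S. pombe. Each alignment was counted as a read, so the 294 and 4 reads with 2 alignments enter with both. The random bases of the adaptor were not used here, so PCR copies could not be removed. Identical alignments were counted once as an alternative, which left 12488 (12.3%) and 6246 (38.7%) alignments. All intervals are 95% Wilson intervals for shares and exact Poisson intervals for counts, and cover counting error only. A count of 0 was given an upper limit of 3 counts.

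S. cerevisiae genes came from the R64 reference, in which 5784 of 6002 protein-coding spans are multiples of 3 and thus end at the stop codon. No intron coordinates came with it. Its introns were taken from alignment gaps of 30 to 3000 nt seen in at least 3 reads, which gave 51 introns. By construction this leaves out introns never seen spliced and those seen spliced in fewer than 3 reads. One of the 51 joins different snoRNA genes, and values without it stand beside those that hold it. S. pombe genes and 5301 introns came from the RefSeq annotation of assembly ASM294v3. The assembly was compared with the alignments first: read ends stayed within chromosomes I to III, all 329 distinct gaps that matched an annotated intron had GT-AG ends, and 0 lay on the opposite strand. The 451 mitochondrial reads were left out of the work on introns. Coordinates are from 1.

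The read's 3' end was taken as the 3' end of the nascent RNA. Finished RNA in the pools was not told apart from nascent RNA, which limits every share of spliced reads. A read was informative for an intron if it began upstream of the 5' splice site and ended downstream of the 3' splice site by at least 1 nt each. It was spliced if it had a gap within 3 nt of both intron ends, and unspliced if 1 block covered the intron. Reads with another gap there (2 in S. cerevisiae, 9 in S. pombe) were left out. The shortest gap in any S. pombe read was 31 nt, while the 18 tRNA introns with reads are 7 to 25 nt long, so a spliced tRNA could not have been recognised. The planned values over all introns hold these 58 tRNA reads as unspliced, and values for protein-coding genes stand beside them. Unspliced molecules are longer than spliced ones. Of the mRNA reads long enough for the spliced form, 17.8% in S. cerevisiae and 23.2% in S. pombe were also long enough for the unspliced form. Loss of long molecules would raise percent spliced, but read lengths also follow from where nascent 3' ends lie, and a loss was not tested.

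Percent spliced was the share of spliced among informative reads, per intron and pooled. Groups were compared by the difference of median percent spliced over introns with at least 10 informative reads, with two-sided permutation tests that were exact where all splits could be listed. Only 5 S. cerevisiae and 13 S. pombe introns had that many reads. Tests on pooled reads of all introns of protein-coding genes, with labels permuted over genes (100000 draws), were added after seeing the data, as was a comparison of introns picked by a spliced read in the earlier or later movies and measured in the others, with 1000 bootstrap draws over genes. Introns and genes are not replicates, so each p describes these pools of reads only. Gene lists were written before the data were examined, with at least 4 measured members needed for a test and Benjamini-Hochberg adjustment within a species. For the distance of the 3' end from the 3' splice site, only 3' ends at or upstream of the stop codon of protein-coding genes were used, in bins of 25 nt, with 1000 bootstrap draws over genes. Neighbouring introns were compared with the intron pair as stratum and 10000 permutations. Read 3' ends on splice sites were set against the mean of the other positions within 10 nt, with Poisson intervals of the count at the site and, added after seeing the data, exact intervals of the ratio that hold the error of both counts. The introns named are those fixed by rule: the 10 S. cerevisiae and 8 S. pombe introns with the most informative reads, the 6 highest and the 6 lowest in percent spliced among introns with at least 20 informative reads, genes of a fixed list of interest with at least 10 informative reads, and the 6 S. pombe genes with the most reads over neighbouring introns, ties included. Other named features were chosen after their values were seen.

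Alternatives covered unspliced reads that start inside the intron, 10 nt of exon on each side, exact gap ends, thresholds of 5 and 20 reads, identical alignments counted once, read 3' ends within the coding span, bins of 10 and 50 nt, end windows of 25 nt, introns of at most 150 nt, and each set of movies. For snoRNAs with at least 50 reads, the commonest 3' and 5' ends were compared with the annotated ends. A read was assigned to a small RNA gene where at least 50% of the read or gene overlapped on the same strand.

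The calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. They were tested on simulated reads over 300 introns with 40 reads each. The intervals held the true percent spliced for 95% of introns, a true difference of 20 points between gene groups came out as 20.2 points, and 4% of relabellings without a difference gave a p under 0.05. Independent introns (100 pairs of 20 reads) gave an odds ratio of 0.989 and linked introns 12.2. The real reads were far fewer, with 794 informative reads over 420 introns of S. pombe protein-coding genes, and the simulated reads had no limit of length. The simulation therefore checks the calculations and not their power or bias in these data. The rule for judging a test of read ends at intron-like sequences inside exons was changed after its counts were seen, because its bound had left out the counting error of the neighbouring positions, which held only 4 reads.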

Results

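Long-read sequencing of nascent RNA was used to read, in single molecules, where the 3' end lay, taken as the point that transcription had reached, and whether the introns behind it had been removed. The data comprised a pool of 101128 alignments (100834 reads) from S. cerevisiae, for which the labels name 2 replicates, and 16126 alignments (16122 reads) from 1 S. pombe sample. The median aligned length was 112 nt in S. cerevisiae (95th percentile 274 nt) and 157 nt in S. pombe (95th percentile 296 nt). A gap in the alignment was present in 493 S. cerevisiae reads (0.488%) and in 620 S. pombe reads (3.84%), of which 94 had at least 2 gaps. There were no replicates to compare within either pool, so intervals cover counting error and p-values describe introns or genes of these pools.

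Small nucleolar RNAs (snoRNAs), the guides of rRNA modification and processing, made up most reads in both yeasts. They held 94.96% of S. cerevisiae reads (95% interval 94.8 to 95.1) and 68.1% of S. pombe reads (67.4 to 68.8). Protein-coding genes held 3.59% (3629 reads) and 16.3% (2635 reads). In S. pombe, genes annotated as long non-coding RNA held a further 8.27%, the mitochondrial genome 2.80% and genes annotated as snRNA 1.99%. The first of these classes includes srp7 (118 reads) and mrp1 (28 reads). In the snRNA class, 134 reads belonged to snR48, an RNA encoded in an intron of rps3. In S. cerevisiae, tRNA genes held 0.745% and snRNA genes 0.127%. A few genes dominated. In S. cerevisiae SNR190 (chromosome X, 139761 to 139950) alone had 11742 reads (11.6%), followed by SNR40 with 8724, SNR9 with 4158, SNR52 with 3315 and SNR128, the U14 RNA needed for 18S rRNA processing, with 3305. In S. pombe snu32 led with 1244 reads (7.71%), ahead of snu3, a U3 RNA, with 1013, snR30 with 984, sno12 with 783 and snoZ7 with 702. The 10 most abundant genes held 44.4% of S. cerevisiae and 40.2% of S. pombe reads. These genes were named for their read counts after the values were seen. Counting identical alignments once lowered the snoRNA share to 62.6% and 38.04%. The S. cerevisiae protein-coding share differed between the earlier movies (1.72%) and the later one (7.08%), whose reads were longer (median 185 nt against 101 nt).

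**Figure D1:**
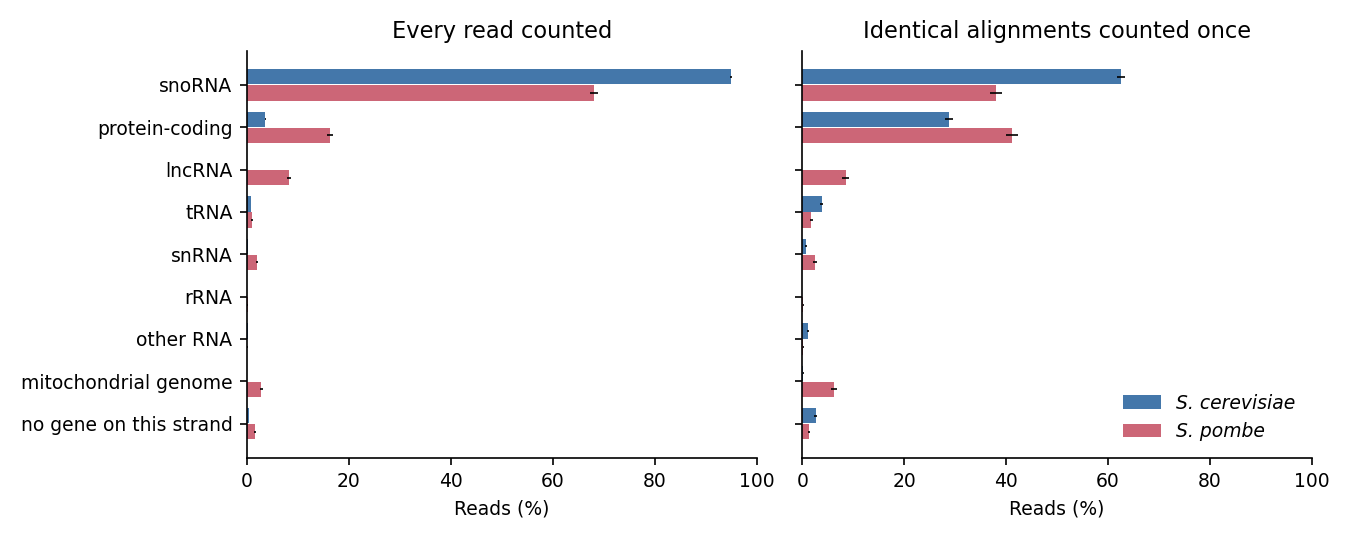
Share of reads (%, horizontal axis) by the class of gene they aligned to on the same strand, for every read (left) and with identical alignments counted once (right), in S. cerevisiae (blue) and S. pombe (red); bars show the share and black lines its 95% Wilson interval. The snoRNA bar falls from 94.96% to 62.6% in S. cerevisiae and from 68.1% to 38.04% in S. pombe when identical alignments are counted once.

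Most snoRNA reads ended at a fixed 3' base. Among the 75 S. cerevisiae snoRNAs with at least 50 reads, the commonest 3' end was the annotated end for 55 and lay within 2 nt of it for 60. In these, 91.8% of the 95841 reads ended within 1 nt of the commonest 3' end, while 79.0% began within 1 nt of the commonest 5' end. Only 409 reads (0.427%, 0.387 to 0.470) ran at least 10 nt past the commonest 3' end. In S. pombe the commonest end matched the annotation less often, exactly for 6 of 38 snoRNAs and within 2 nt for 24, and 86.2% of 10602 reads ended within 1 nt of the commonest 3' end against 57.3% at the 5' end. The latter share was lowered by snu32, snu3 and snR30, of whose reads 12.4%, 11.9% and 10.8% began there. Some of the 38 genes are longer transcripts that hold another annotated snoRNA. The commonest 3' ends of SPNCRNA.723 and SPNCRNA.1394 lay 622 and 197 nt before the annotated ones, close to the annotated ends of snR41 and snR3 inside them. The lower match to the annotation thus follows in part from the assignment of reads to genes. The median over snoRNAs was 90.7% at the 3' end and 79.3% at the 5' end in S. pombe, and 93.6% and 72.5% in S. cerevisiae. The largest departures among S. cerevisiae genes were SNR41, whose commonest 3' end lay 15 nt past the annotated one, and SNR81, 13 nt before it. These genes were singled out after their values were seen.

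In S. cerevisiae nearly all informative reads were spliced. Over 51 gaps taken as introns, 411 of 425 informative reads (96.7%, 94.5 to 98.0) lacked the intron. These include a gap of 5 reads that joins the snoRNA genes SNR77 and SNR73 and lies in no single gene, and without it the share was 96.7% of 420 reads. The genes of the U3 snoRNA, which is needed for early cleavages of pre-rRNA and is encoded with an intron, gave the deepest values: SNR17A (XV, intron 780121 to 780277) was spliced in 129 of 132 reads (97.7%, 93.5 to 99.2) and SNR17B (XVI, 281374 to 281503) in 36 of 37 (97.3%, 86.2 to 99.5). Among protein-coding genes 241 of 251 reads were spliced (96.0%, 92.8 to 97.8), and 46 of these 48 genes encode ribosomal proteins. RPL25 (XV, 80361 to 80774) was spliced in 13 of 13 reads, RPS17A (XIII, 225892 to 226289) in 11 of 11, RPL43A (XVI, 654168 to 654570) in 10 of 10 and RPL35A (IV, 117667 to 118157) in 9 of 9. RPL13B (XIII, 550802 to 551203) and RPL20A (XIII, 753743 to 754219) were each spliced in 7 of 7. RPL40A (IX, 68716 to 69149), which encodes a ubiquitin fusion, was spliced in 8 of 9 reads. RPL32 (II, 45645 to 45977) was the lowest of the introns named, with 5 of 8 reads spliced (62.5%, 30.6 to 86.3). Because S. cerevisiae introns were found through at least 3 spliced reads, introns never or seldom seen removed are not represented. Read length is a further limit: 28.1% of mRNA reads were as long as the median intron of spliced mRNA reads (405 nt). Unspliced reads over such introns may have been missed, which was not tested. With gaps of at least 1 read, 491 of 515 reads in 110 gaps were spliced (95.3%). The median of the 5 introns with at least 10 reads was 100%.

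In S. pombe most informative reads of mRNA genes were spliced. Introns came from the annotation there, so that introns never seen spliced were counted too, unlike in S. cerevisiae. Over 420 introns of protein-coding genes, 652 of 794 informative reads were spliced (82.1%, 79.3 to 84.6). Several ribosomal protein introns were spliced in all or all but 1 of their reads: rps2502 in 24 of 25 reads at its first intron (I, 4208795 to 4208844) and 16 of 16 at its second (I, 4208501 to 4208553), rpl35 (III, 89137 to 89420) and rps1702 (III, 917867 to 917930) each in 14 of 14. In rpl4102 (I, 2853797 to 2853848) it was 10 of 12 (83.3%, 55.2 to 95.3). The non-coding gene snoR61 (II, 3874462 to 3874797), which carries a snoRNA, was spliced in 28 of 28 reads (100%, 87.9 to 100). A further 4 reads held another gap with the same 3' splice site and are not among the 28. The introns of snoR61 (336 nt) and rpl35 (284 nt) are long for this library, whose longest read was 356 nt and 95th percentile 296 nt. Unspliced reads over them could hardly have been seen, so their values of 100% cannot measure how completely they were spliced. The gene of U6, the spliceosomal RNA of the catalytic core, has an mRNA-type intron in fission yeast (I, 2562324 to 2562373, starting GTAAGT and ending TAG), and 25 of its 45 informative reads were spliced (55.6%, 41.2 to 69.1). These reads ended near the 3' end of the U6 gene, a median of 53 nt past the 3' splice site, and with identical alignments counted once the share was 53.3% of 30. Over all 441 introns with reads, tRNA genes included, 706 of 926 reads were spliced (76.2%, 73.4 to 78.9), and the median of the 13 introns with at least 10 reads was 96.0% (bootstrap 81.8 to 100). None of the 58 tRNA reads was called spliced, among them 12 of tRNA-Ala.06 (I, 4797013 to 4797023), but these introns are shorter than any gap in the alignments and the value cannot be read as a lack of splicing.

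**Figure D2:**
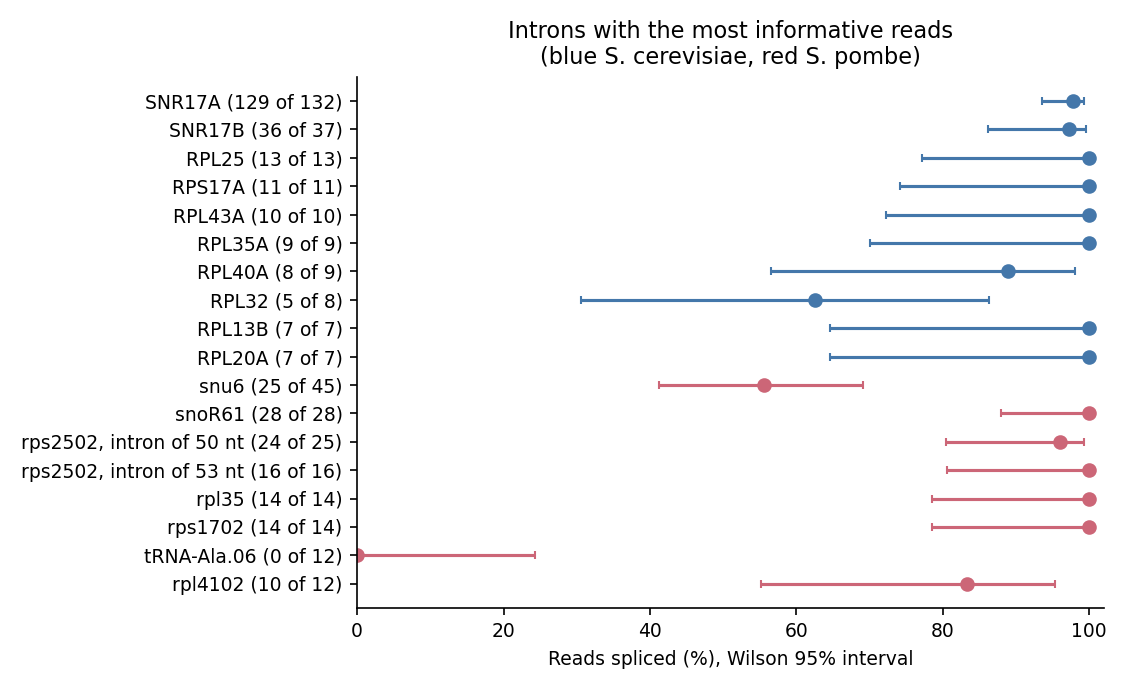
Percent of informative reads that were spliced (horizontal axis) at the introns with the most informative reads, with spliced and informative reads beside each name; points are single introns and lines 95% Wilson intervals, in blue for S. cerevisiae and red for S. pombe. The U6 gene snu6 stands at 55.6%, and most of the other introns lie above 80%. The value of tRNA-Ala.06, an intron of 11 nt, is not a measure of splicing. Few S. pombe reads were long enough to show the introns of snoR61 (336 nt) and rpl35 (284 nt) unspliced.

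The species comparison asks whether nascent introns are removed to the same extent in both yeasts. The median percent spliced over introns with at least 10 reads was 100% in S. cerevisiae (5 introns) and 96.0% in S. pombe (13 introns), a difference of 4 points that did not pass the threshold (two-sided exact permutation p = 0.326). With reads pooled over protein-coding genes, the S. cerevisiae share was 13.9 points higher (96.0% of 251 reads in 48 genes against 82.1% of 794 reads in 332 genes, permutation p = 0.0037). That test was added after seeing the data and sets introns found through spliced reads in S. cerevisiae against all annotated introns in S. pombe. With introns found through at least 3 spliced reads in both species, the difference was 1.06 points (96.0% against 94.96%, permutation p = 0.604). That rule selects S. pombe introns on having been spliced, so their share had to rise, and it raised the part of ribosomal protein genes among their informative reads from 40.7% (323 of 794) to 82.9% (296 of 357).

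Ribosomal protein genes, the most strongly transcribed intron-containing genes of both yeasts, were compared with all other genes. In S. pombe their introns were spliced in 305 of 323 reads (94.4%, 91.4 to 96.4) against 347 of 471 reads (73.7%, 69.5 to 77.4) in 276 other protein-coding genes. The difference of 20.8 points passed a permutation test over genes (p = 2.40e-04), which was added after seeing the data. It was 24.3 points in the earlier movies (p = 1.90e-04) and 18.1 points in the later ones (p = 0.0013), by the same permutation test. Both sets of movies come from the same sample, so they are not replicates. Of the reads long enough for the spliced form, 19.3% were also long enough for the unspliced form at ribosomal protein introns and 26.5% at the others; with introns of at most 150 nt the difference was 22.9 points (permutation p = 0.0014). The planned test over genes with at least 10 reads per intron gave a difference of medians of 42.4 points (9 against 3 genes, two-sided exact permutation p = 0.0455). The 3 other genes there were U6, snoR61 and tRNA-Ala.06, so it compared no mRNA genes, and without the tRNA the difference was 20.2 points (exact permutation p = 0.236). In S. cerevisiae the planned test set 3 ribosomal protein genes against the U3 genes SNR17A and SNR17B, a difference of 2.49 points with an exact permutation p of 0.1, the smallest this design allows. With reads pooled over all gaps, ribosomal protein genes were spliced in 292 of 306 reads (95.4%) and 23 other protein-coding genes in 29 of 35 (82.9%), a difference of 12.6 points (permutation p = 7.20e-04, added after seeing the data). That call was lost when 3' ends past the stop codon were left out (7.80 points, permutation p = 0.0759) and in the earlier movies alone (5.66 points, permutation p = 0.526), while the later movie gave 15.1 points (permutation p = 0.0018). Every S. cerevisiae gene in these pooled tests entered through at least 1 spliced read. That rule sets more of the share where a gene has few reads, so the tests cannot decide whether the groups differ.

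Of the other S. pombe gene lists, none passed the threshold after adjustment, over 8 lists tested on pooled reads in permutation tests added after seeing the data. Genes of the secretory pathway were spliced in 14 of 22 reads (63.6%, 43.0 to 80.3, permutation p = 0.0534, adjusted p = 0.189 over the lists), with unspliced reads in vps1302, apl1, apm3, sec28, sec6102, vps1 and vps15. Genes of pre-mRNA splicing were spliced in 13 of 21 reads (61.9%, 40.9 to 79.2, permutation p = 0.0707, adjusted p = 0.189), with unspliced reads in prp19, smg1, srp2, lsm2, lsm7, lsm8 and smb1. The members were named after their values were seen. Against all other genes the secretory pathway differed by -19.0 points and pre-mRNA splicing by -20.8 points. With ribosomal protein genes left out of the other genes, these were -10.5 points (permutation p = 0.359) and -12.3 points (permutation p = 0.368). Cytoskeletal genes had 18 of 22 reads spliced, ubiquitin and proteasome genes 11 of 14, genes of mitochondrial proteins 24 of 28, chromatin and transcription genes 10 of 14 and translation factors 14 of 16. The ribosomal protein list had an adjusted p of 0.0019. In S. cerevisiae 4 lists could be tested. Each of these genes entered through at least 1 spliced read, and most had few reads, so the tests cannot decide whether a list differs. The ribosomal protein list passed (adjusted permutation p = 0.0029), and the secretory pathway was lower than all other genes (5 of 7 reads spliced, 71.4%, adjusted permutation p = 0.0285), while the difference from other genes without ribosomal protein genes (71.4% against 85.7%) did not pass the threshold (adjusted permutation p = 0.759). Hosts of intronic snoRNAs had 10 of 12 reads spliced and cytoskeletal genes 7 of 8, with adjusted permutation p of 0.137 and 0.194. Translation factors (3 of 4 reads), mRNA processing and export (1 of 1) and chromatin and transcription (3 of 3) had too few members measured, and meiosis, ubiquitin and proteasome, and mitochondrial proteins had 0 reads.

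The distance between the 3' splice site and the read's 3' end was taken as how far transcription had gone when an intron was already removed. This holds for nascent RNA only, and reads of finished RNA in the pools were not told apart. In S. pombe mRNA genes 1 of 8 reads was spliced at 1 to 10 nt (12.5%, 2.24 to 47.1) and 42 of 53 at 11 to 25 nt (79.2%, 66.5 to 88.0). The share was 84.5% at 26 to 50 nt (58 reads), 74.8% at 51 to 100 nt (147 reads), 76.5% at 101 to 200 nt (260 reads) and 93.2% at 201 to 500 nt (147 reads). An unspliced read holds the intron besides this distance, and the longest S. pombe read was 356 nt. Unspliced reads could thus seldom be seen at 201 to 500 nt. The higher share there, and the overlap of gene groups in that bin, cannot be told apart from this limit. The first bin of 25 nt already held 70.5% spliced reads, so 50% was passed within 25 nt, and within 20 nt with bins of 10 nt (bootstrap over genes 20 to 20). Ribosomal protein and other genes overlapped in their intervals at 11 to 25 nt (75% of 16 and 81.1% of 37 reads), at 26 to 50 nt (91.7% of 12 and 82.6% of 46) and at 201 to 500 nt (96.9% of 64 and 90.4% of 83). They stood apart at 51 to 100 nt (95.5% of 44, interval 84.9 to 98.7, against 66.0% of 103, 56.4 to 74.4) and at 101 to 200 nt (94.4% of 89 against 67.3% of 171). In S. cerevisiae no read ended within 25 nt of a 3' splice site. There, 3 of 5 reads were spliced at 26 to 50 nt, 26 of 28 at 51 to 100 nt (92.9%), 56 of 60 at 101 to 200 nt (93.3%) and 79 of 80 at 201 to 500 nt (98.8%). Read length limits unspliced reads here too, since the median intron of spliced mRNA reads was 405 nt and the median mRNA read 280 nt. These introns were found through at least 3 spliced reads, while the S. pombe bins hold all annotated introns, so the bins cannot be compared between species. With introns found through at least 3 spliced reads in both species, pooled shares for these 3' ends were 94.9% in S. cerevisiae and 94.6% in S. pombe. That comparison (permutation p = 0.904) was added after seeing the data and selects introns on having been spliced. The shortest downstream exon part of a spliced read was 9 nt in S. pombe and 39 nt in S. cerevisiae, where few reads ended that close to a 3' splice site. Whether shorter parts would have been aligned was not tested. Each species had only 4 reads at 501 to 1000 nt, too few to set the level there.

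**Figure D3:**
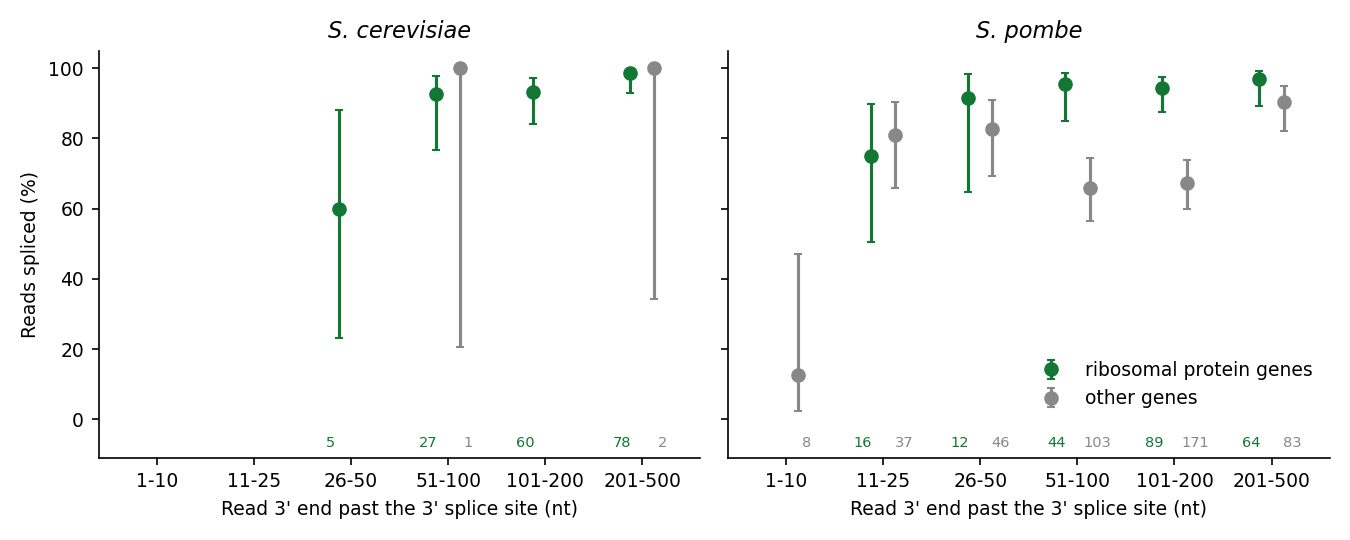
Percent of informative reads that were spliced (vertical axis) by the distance of the read's 3' end past the 3' splice site (nt, horizontal axis), for S. cerevisiae (left) and S. pombe (right), in ribosomal protein genes (green) and other protein-coding genes (grey); points are pooled reads, lines 95% Wilson intervals, and the figures along the bottom the informative reads. In S. pombe the groups are 75% and 81.1% at 11 to 25 nt and 95.5% and 66.0% at 51 to 100 nt. S. cerevisiae introns were found through at least 3 spliced reads and S. pombe introns came from the annotation, so the panels cannot be compared with each other.

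Intron length and percent spliced were compared in each species. Across the 13 S. pombe introns with at least 10 reads, which include tRNA-Ala.06, Pearson's r was 0.419 (permutation p = 0.131) and Spearman's rho 0.670 (permutation p = 0.0148), and r was 0.354 without the 2 introns farthest from the median length. Without tRNA-Ala.06, whose value is not a measure of splicing, neither passed the threshold: rho was 0.573 (permutation p = 0.0547) and r 0.367 (permutation p = 0.247), or 0.154 without the 2 introns farthest from the median length. Across 37 S. pombe introns with at least 5 reads, rho was 0.768 (permutation p = 1.00e-05) and r 0.51 (permutation p = 0.0023). No tRNA intron was left out there, neither tRNA-Ala.06 nor any other with enough reads. All tRNA introns are short and none could be called spliced, which raises the relation. It was not computed without them at this threshold, so it cannot be read as a relation with splicing. Across 27 S. cerevisiae gaps with at least 5 reads, rho was 0.460 (permutation p = 0.0162) and r 0.179 (permutation p = 0.346). The longest of them was the SNR77 to SNR73 gap of 716 nt, and across the other 26 rho was 0.452 (permutation p = 0.0206) and r 0.163 (permutation p = 0.423). Introns are not independent replicates, and at the planned threshold only the S. pombe relation was computed, since 5 S. cerevisiae introns were too few. Unspliced reads over longer introns must be longer, and their loss alone could give a positive relation. Of S. cerevisiae mRNA reads, 28.1% were as long as the median intron of spliced reads (405 nt), and the longest S. pombe read was 356 nt. These relations therefore cannot show that longer introns are spliced more fully. With at least 10 reads at both, the first and last introns could be compared in rps2502 alone, with 96.0% of 25 reads and 100% of 16 reads spliced. With unspliced reads allowed to start inside the intron, the first was spliced in 82.8% of 29 reads. With at least 5 reads rpl3801 was added, with 100% of 7 and 100% of 6 reads spliced.

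Reads that spanned 2 neighbouring S. pombe introns mostly had both or neither removed. There were 130 observations of a read at an intron pair, from 108 reads in 72 genes. Both introns were spliced in 110 observations, neither in 10, only the first in 6 and only the second in 4, so 92.3% (86.4 to 95.8) had the same state. With each read counted once the share was 92.6% of 108 (86.1 to 96.2). All 12 reads of rps2502, all 5 of rpl3801 and all 4 of rps29 had both introns removed. Of the genes with 3 reads, nda3, which encodes beta-tubulin, cox7, a cytochrome c oxidase subunit, and cct6, a subunit of a chaperonin, had every spanned intron removed in all 3, and smg1 in 2. In sce3 all 3 reads had kept both introns. In rpb1, the gene of the largest subunit of RNA polymerase II, 1 read spanned 5 introns and kept the second alone, a gene picked out after its values were seen. The planned test within intron pairs had no power, since no pair had reads that varied at both introns (permutation p = 1). Pooled without strata, the expected share was 79.6% and the odds ratio 45.8 (permutation p = 1.00e-04, the smallest that the draws allow), a value that includes differences between genes and counts some reads more than once. With each read counted once the odds ratio was 60 with the same permutation p. Of the 10 observations with exactly 1 intron removed, from 9 reads, 6 had lost the first (60%, 31.3 to 83.2), and a departure from equal order did not pass the threshold over 9 genes (exact sign-flip permutation p = 0.727).

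Read 3' ends piled up on the last base of exons upstream of S. pombe introns. There were 99 such reads where 4.1 were found on average at the other positions within 10 nt, a ratio of 24.1 (19.6 to 29.4, or 17.8 to 32.8 with the counting error of the other positions), and they came from 92 introns of 92 genes with at most 2 in an intron. The base before held 14 reads and the base after 3. The ratio was 24.3 in the earlier movies (45 reads) and 24.0 in the later ones (54 reads). Ribosomal protein genes gave 7.07% (3.47 to 13.9) of these reads but 46.8% of the spliced reads of protein-coding genes. The last intron base, where an excised intron would end, held 1 read, a ratio of 0.667 (0.0169 to 3.71). In S. cerevisiae the planned ratio at the last exon base was 1.31 (1.10 to 1.55), from 141 reads, nearly all at a gap that starts at the end of SNR77, and it was 0.714 (0.343 to 1.31) in the later movie. Without that gap there were 6 reads at the site and 3 at all other positions together, a ratio of 40 whose interval with the error of both counts was 8.54 to 247. With gaps of at least 1 read the ratio was 1.33 with that gap and 15 without it (5.58 to 38.8 by the same interval). Its last intron base held 1 read, a ratio of 1.67 (0.0422 to 9.29), but with gaps of at least 1 read it held 10, a ratio of 6.90 (3.00 to 14.6 with the error of both counts).

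**Figure D4:**
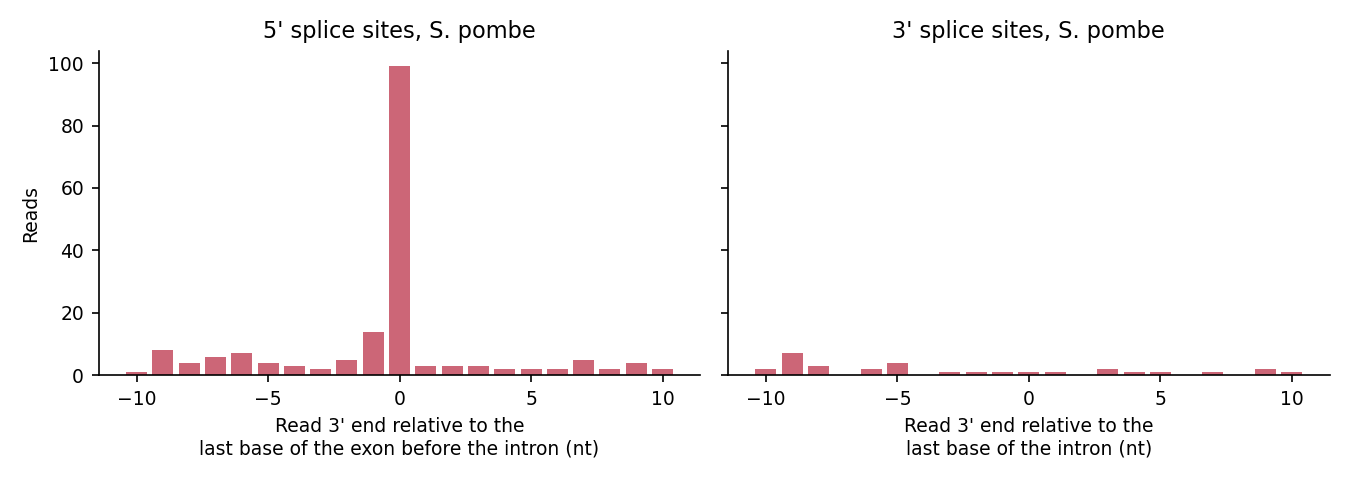
Number of S. pombe reads (vertical axis) by the position of their 3' end in nt from the last base of the exon before an intron (left) and from the last base of the intron (right), summed over introns. The last exon base stands out with 99 reads, against 14 at the base before it and 1 at the last intron base.

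Few reads ended far past the stop codon in either splicing state. More than 300 nt past the stop codon, 0 of 10 unspliced S. cerevisiae reads (which allows up to 30%) and 0 of 241 spliced reads (up to 1.24%) ended, and in S. pombe 0 of 132 unspliced (up to 2.27%) and 1 of 532 spliced reads. The planned odds ratio could not be formed. In S. pombe the 95th percentile of mRNA read lengths was 321 nt, so few reads there could reach from an intron to that distance. Counting any 3' end past the stop codon, 5 of 132 unspliced (3.79%) and 82 of 532 spliced reads (15.4%) qualified in S. pombe, and 1 of 10 (10%) against 73 of 241 (30.3%) in S. cerevisiae. Within genes neither difference passed the threshold (permutation p = 0.332 and 0.595). Those counts were added after seeing the data.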

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

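The test of the gap between SNR77 and SNR73 was chosen after the reads had been seen. In the snoRNA cluster on S. cerevisiae chromosome XIII, 5 reads (Poisson interval 1.62 to 11.7; 3 distinct alignments, 3 reads from the earlier movies and 2 from the later one) had a gap of 716 nt from 297590 to 298305, which joins different snoRNA genes. By the rule for gaps it stood among the 51 S. cerevisiae introns, with 5 of the 425 pooled reads, and entered the relation with intron length and the exon-end ratio, but no test of ribosomal protein or other protein-coding genes. The count of 5 exceeds the limit that a count of 0 allows. It runs from the end of SNR77 to the start of SNR73, each within 1 nt of the commonest end of the mature snoRNA, so that the SNR76, SNR75 and SNR74 genes between them are missing. If abundant snoRNA molecules were joined at random in the library, the rate of reads with 2 alignments and the shares of both snoRNAs would give 0.0598 such reads, well below the lower bound of the count. A join favoured between neighbouring templates, in the cell or during cDNA synthesis, may still account for it, as may an aligner that joins close pieces more readily than distant ones. No biological explanation was tested, since the design gives none.

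In S. cerevisiae 294 read names had 2 separate alignments, 243 of them with both in snoRNA genes, and 280 came from the later movie against 14 from the earlier ones. In S. pombe there were 4.

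Another 32 S. cerevisiae reads spanned at least 2 snoRNA genes without a gap (0.0333% of snoRNA reads, 0.0236 to 0.0470), as an uncut precursor would: 10 ran from SNR74 to SNR73, 6 from SNR190 to SNR128, 5 from SNR41 to SNR70, 4 from SNR78 to SNR77 and 3 from SNR76 to SNR75. S. pombe had 1 such read, from snoZ5 to snoZ4.

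Among 24 S. pombe gaps that did not match an annotated intron to the base, 17 with GT-AG ends, 6 lay within 3 nt of an annotated intron at both ends and were counted as that intron. The most frequent of the 24 had 4 reads (II, 3874462 to 3874625) and shares the 3' splice site of the annotated intron of snoR61. A gap of 41 nt in cox7 (II, 1715443 to 1715483) had 3 reads and is the annotated intron (1715443 to 1715482) with 1 end shifted by 1 nt. A gap in fps1 (I, 1339701 to 1339868) had 2.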

How the results depend on the processing

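The settings by movie, without tRNA introns, on protein-coding genes alone, with S. pombe introns from gaps, with gaps of at least 1 read, on pooled reads, without strata, with each read counted once, with bins of 10 nt and without the SNR77 gap, every alternative for the snoRNA share and the U6 intron, and intervals with the error of both counts, were chosen after seeing the data; the others were planned. Over 24 results and 161 alternatives, 128 values stayed within the counting interval or on the same side of the threshold and 1 called value reversed, the S. cerevisiae exon-end ratio of 1.31, which was 0.714 in the later movie. Among values without a call, the share with the first intron removed went from 60% to 0% for first and last introns, from 1 read, and the S. pombe ratio at the last intron base from 0.667 to 1.33 in the earlier movies. Counting identical alignments once moved the snoRNA share to 62.6% and 38.04%, the S. cerevisiae exon-end ratio to 4.13, the S. pombe ribosomal protein difference to 21.2 points (exact permutation p = 0.236) and the lists past the threshold to 0, while the same difference on pooled reads of protein-coding genes was 20.5 points (permutation p = 2.40e-04). The S. cerevisiae snoRNA share was 96.6% in the earlier movies and 91.9% in the later one, whose median percent spliced was 96.4%. Unspliced reads allowed to start inside the intron lowered the pooled S. cerevisiae share to 89.5% and took the difference between the first and last introns of rps2502 from -4 to -17.2 points. The pooled S. pombe share was 79.9% for 3' ends within the coding span, 81.3% without tRNA introns, 82.1% for protein-coding genes and 91.2% for introns from gaps. Bins of 50 nt put the 50% point at 50 nt. The following differences passed the threshold only where several choices changed together, to pooled reads of protein-coding genes without a minimum per intron: the species difference with annotated S. pombe introns (13.9 points; 1.06 with gaps in both species did not pass) and, with gaps of at least 1 read, the S. cerevisiae ribosomal protein difference (12.6 points, later movie 15.1; 5.66 in the earlier movies and 7.80 for 3' ends up to the stop codon did not pass). The S. pombe ribosomal protein difference lost it without tRNA introns (20.2 points), as did the rho of intron length (0.573). With at least 20 reads the ribosomal protein difference was 18.2 points (exact permutation p = 1). There rps2502 alone stood against U6 and snoR61, so that test could not have passed. The share of reads with both or neither intron removed passed the threshold in each setting without strata, at 92.3% for all observations, 92.6% with each read counted once, and 92.5% and 92.2% in the earlier and later movies, where gene differences enter. The S. cerevisiae exon-end ratio was 3.27 in a window of 25 nt, 68.7 within 1 nt and 1.33 for gaps with at least 1 read, and without the SNR77 gap, where snoRNA ends set it, 40, or 15 for gaps with at least 1 read. The S. pombe ratio was 35.1 in the wider window and 10.7 within 1 nt. At the last intron base, the S. cerevisiae ratio was 0 in the earlier movies and the S. pombe ratio 0 in the later ones, from single reads, and with gaps of at least 1 read the S. cerevisiae ratio was 6.90 from 10 reads. Other causes were not tested. No paired analysis was possible because the S. cerevisiae replicates stand in 1 pool that does not tell them apart and S. pombe has 1 sample, so leaving out a replicate was not run either. Thresholds that left too few introns or genes on a side gave no value, and depth limited every value per intron.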

Other observations

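The comparison among ribosomal protein genes alone, the one of introns picked in other movies and the pooled species comparison below were tests chosen after results were seen. Introns with at least 50 reads wholly inside them were picked, and those of them that host a snoRNA were seen mainly as that snoRNA. In S. cerevisiae the intron of EFB1, which encodes a translation elongation factor (I, 142254 to 142619), held 2540 reads that lay wholly inside it, 2539 of them assigned to SNR18, beside 3 spliced and 1 unspliced read of the host. The intron of RPS22B (XII, 856575 to 857057) held 2222 reads of SNR44 beside 1 spliced read, that of ASC1 (XIII, 499879 to 500151) 291 of SNR24 and that of RPL7A (VII, 364965 to 365432) 144 of SNR39. In S. pombe the same was seen for nog2, a ribosome assembly GTPase, with 275 reads of snR191, rpl701 with 161 of snoR39b, rps3 with 132 of snR48, fta3 with 128 of snoR47, cpc2 with 117 of snoU24b and spt20 with 77 of snoU24. The host reads were 4 spliced and 0 unspliced for rpl701 and 11 spliced and 0 unspliced for rps3.

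Several S. pombe snoRNA genes had reads far from their annotated ends. Of snu3 reads, 82.1% ended on 1 base 123 nt before the annotated 3' end, and the commonest 5' end lay 122 nt before the annotated start. The commonest 3' end lay 330 nt before the annotated end in snR90, 53 nt past it in snR191 and 21 nt past it in snoU24. SNR190 and SNR128, neighbours on S. cerevisiae chromosome X, differed in share between movies: SNR190 held 8.12% of reads in the earlier movies and 18.1% in the later one, and SNR128 held 3.62% and 2.61%. Reads of the later movie were longer (median 185 nt against 101 nt), and SNR190 is annotated as 190 nt and SNR128 as 126 nt. A difference between the genes thus cannot be told apart from one in read length. Whether the earlier and later movies correspond to the 2 replicates is not known. In the lists of S. pombe genes, tef5 was spliced in 6 of 6 reads and tif301 in 4 of 5.

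The 99 S. pombe reads that end on the last exon base before an intron are where the cut exon of the first splicing step would end, which the design gives no group to test; no biological explanation was tested. If they were spliced reads whose short second exon was clipped, the aligned part would run on by a base wherever the intron and the next exon start with the same base, leaving at most 5% of the reads at such introns. The share was 23.2% (16.01 to 32.5), close to the 28.1% of introns of that kind, which argues against clipping as the whole cause. Clipping of some of them remains possible, since spliced reads with a second exon of 1 to 11 nt numbered 1 and those with 12 to 22 nt numbered 31. A preference of read ends for the bases at intron starts cannot be told apart: 0 reads ended before the same hexamers at 1728 exon positions, but the windows around them held only 4 reads in all (against 116 at introns, two-sided Fisher's exact p = 0.0415 for the share at the site), and the bound fixed beforehand had left out the counting error of those 4. With it the ratio inside exons could reach 30.3, above the lower bound of 17.4 at introns with these hexamers.

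The lower pooled share of spliced reads in S. pombe mRNA genes cannot be told apart from a difference in how introns were found. At introns picked by a spliced read in 1 set of movies and measured in the other, with S. pombe gene classes weighted as among annotated introns, the difference of 13.9 points was 8.70 points (bootstrap over genes 3.00 to 15.4), an interval on both sides of the bound of 6.95 points, and it still holds the gene mix, since 235 S. cerevisiae reads came from ribosomal protein genes and 5 from others. The shares at these introns were 95.3% against 94.3% in S. pombe for ribosomal protein genes and 40% (2 of 5 reads) against 79.4% for others, and among ribosomal protein genes with annotated S. pombe introns the difference was 1.88 points (permutation p = 0.395), so the S. cerevisiae pool, in which few other genes were measured, may differ by its gene content. Loss of long unspliced molecules cannot be told apart either: 17.8% of S. cerevisiae mRNA reads long enough for the spliced form were also long enough for the unspliced form, against 23.2% in S. pombe, a ratio between the bounds that had been set. A difference between the species in splicing itself stays open.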
